A study of Mus musculus with 4 samples.

How the data were processed

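Colon intraepithelial lymphocytes of mice were sorted as live CD3+ CD8α+ cells with TCRβ or with TCRγ, read here as TCRγδ, and each of the 4 libraries was made with a droplet-based 3′ single-cell kit, per the labels' protocols. The deposited matrices hold whole UMI counts per gene and cell, 1 matrix per library, with gene symbols and no gene identifiers. The submitters' processing notes name Seurat 3.0.0 and the GRCm38 and mm10 builds without saying what each was used for. The files list 14661, 14323, 13331 and 13677 genes for TCRβ Tcf7WT, TCRβ Tcf7KO, TCRγδ Tcf7WT and TCRγδ Tcf7KO, 15301 in any library and 12698 in all 4. No symbol names a mitochondrial or ribosomal protein gene, and each library lists its own genes. The rule behind the listing is not known, and a gene that a library does not list gets no value there. Of the symbols, 97.7% were found in the GENCODE M21 annotation of GRCm38, which gave the coordinates.

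UMIs were summed over all cells of a library and divided by the library's total to give CPM. A log2 ratio of CPM has an exact 95% interval conditional on both counts, a CPM has an exact Poisson interval and a share of cells has an exact Clopper-Pearson interval. All of these cover counting error only. With 1 library per group, no test was made, and cells were not used as replicates. The comparisons were Tcf7KO against Tcf7WT within each sort, TCRγδ against TCRβ within each genotype, and the genotype ratios of both sorts across genes. Total depths were 6195292 to 20289960 UMIs, and at these depths the interval of Tcf7 was 143 to 153 CPM in the library with the most UMIs and 40.5 to 51.3 CPM in the library with the fewest. A ratio against a count of 0 would be taken against a floor of 3 UMIs.

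The comparisons, the gene lists, the naming rule and most alternatives were set before the data were examined. Genes were named by size alone: Tcf7, the 10 highest and 10 lowest log2 ratios between genotypes and the 6 highest and 6 lowest between sorts, among genes listed in both libraries with at least 100 UMIs over both and at least 50 CPM in the higher one. Receptor and immunoglobulin segments, mitochondrial, ribosomal, haemoglobin and sex genes and unnamed gene models were left out of this ranking. From each list, the 4 members with the largest absolute ratio and at least 50 UMIs could be named. There were 21 lists. They began with naive and memory, cytotoxic, NK receptor signalling, tissue residency, inhibitory and exhaustion, T cell receptor signalling, and immediate-early and stress genes. Then came interferon response, cell cycle, type 17, type 1, cytokine receptors, Wnt and TCF partners, and regulatory and repair genes. The rest were glycolysis, oxidative phosphorylation, cholesterol and lipid, αβ receptor constant, γδ receptor constant, coreceptors and sex-linked genes. The inhibitory and exhaustion list holds receptors and other genes, such as Tox, Nr4a2, Nr4a3, Lax1 and Cish. A list is described by the median log2 ratio of its members with at least 20 UMIs. The percentile of that median is its place among 10000 random lists of the same size matched on expression in 20 bins, and its interval comes from 1000 redraws of the counts. The ratios of both sorts were correlated over genes with at least 100 UMIs in each.

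Cells with at least 200 genes were clustered together on 2000 variable genes, 30 components and 15 neighbours. The Leiden method (leidenalg 0.10.2) was run at a resolution of 0.5 on a graph of shared neighbours. Scrublet doublets were called with scanpy 1.11.5. Receptor segments, Tcf7, cell cycle and sex genes were left out of the variable genes. Clusters were named from 15 marker sets, by markers among the leading genes and by markers detected, and part of this naming rule was written after the data were seen. Shares of cells by cluster come from a second clustering, added after the data were seen, that left out the 4956 genes at least 1.5-fold apart between genotypes in either sort after 0.5 UMIs were added, with no count minimum. The cytotoxic-like share of the first clustering is not given, since the genes that define that cluster are among those apart. The second clustering lessens this problem and does not remove it. Its cytotoxic-like cluster is still led by Gzma, Gzmb, Tmprss6 and Tnfrsf9, which stood apart, and is named by the first 2 of them. Genes less than 1.5-fold apart stayed in. For shares of cells with a UMI, each cell was thinned to 1624 UMIs, the 10th percentile of TCRβ Tcf7WT, the library with the lowest median UMIs per cell, and cells under that depth were left out.

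The alternatives were TMM (edgeR 4.0.16) and DESeq2 1.42.0 size factors, a total without receptor and immunoglobulin genes, each cell weighing the same, cells with 500 to 3500 genes, no Scrublet doublets, no cells with 2 or more marker UMIs of other types, no cycling cells, thinned cells, clusters weighted alike, other UMI minimums, resolutions of 0.3 and 1, 1000 variable genes and thinning to 1000 UMIs. No scaling moved the median gene by more than 0.1 on the log2 scale. Weighting clusters alike gives a small cluster the weight of a large one, with a minimum of 20 cells per cluster and 1 CPM added. It used 8 clusters for the genotypes in the TCRβ sort and 3 in the TCRγδ sort. Between the sorts it used 4 in Tcf7WT and 3 in Tcf7KO. The procedure was tested on simulated data with known ratios at the depth of these libraries. Counts were drawn per library as Poisson counts, which the intervals also assume, so coverage near 95% follows from the setting. UMIs that gather in single cells were not simulated. Genes changed 2-fold were all lowered, and genes changed 4-fold were all raised. In the TCRβ simulation of 10764 genes, 95.5% of intervals of unchanged genes and 96.5% of those of changed genes held the true ratio. Counted in the direction of the change, genes changed 1.5-fold, 2-fold and 4-fold had median log2 ratios of 0.58, 1.00 and 2.01. In the TCRγδ simulation of 9219 genes these values were 95.5%, 93.0%, 0.59, 0.95 and 2.01. The rule took 20 changed genes of 20 in each, and a list of 15 raised genes reached percentile 100, while a list of 15 unchanged genes lay at 83.1 and 87.0. The raised genes were raised 1.5-fold or 4-fold, so the percentile of a list with a smaller shift was not tested. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.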

Results

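Intraepithelial lymphocytes (IELs), the T cells that sit within the lining of the gut, were sorted from mouse colon and profiled by droplet-based 3′ single-cell RNA sequencing. The labels give 4 libraries. TCRβ+CD8α+ cells and TCRγδ+CD8α+ cells were each given as Tcf7WT and as Tcf7KO. The cell type label of the latter names TCRγ alone, and it was read as TCRγδ, as in the sample titles. The labels give the same strain, with a floxed Tcf7 and an E8I-driven Cre recombinase, to all 4 libraries, so Tcf7WT and Tcf7KO are told apart here by the genotype label alone. Tcf7 encodes TCF-1, a transcription factor of naive and memory T cells. The files held 7603 cells for TCRβ Tcf7WT, 5785 for TCRβ Tcf7KO, 1888 for TCRγδ Tcf7WT and 1511 for TCRγδ Tcf7KO. Total UMIs (unique molecular identifiers, each standing for a captured transcript) were 20289960, 18372180, 6195292 and 7184668 in the same order, and median UMIs per cell were 2431, 2860, 3188 and 4366. Each group was 1 library, so no difference below has a replicate check and none was tested. Levels are given as CPM, a gene's UMIs over all cells of a library scaled to a common library total, and ratios are of CPM. Intervals are 95% intervals that cover counting error only, exact for levels, ratios and shares and from redraws of the counts for list medians. The interval of a ratio of median depths comes instead from redraws of the cells.

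Tcf7 was lower in the Tcf7KO library of both sorts and was not absent from either. In the TCRβ sort it stood at 107 CPM (interval 102 to 112) in Tcf7KO against 148 CPM (143 to 153) in Tcf7WT, a log2 ratio of -0.47 (-0.55 to -0.39). In the TCRγδ sort it stood at 14.6 CPM (11.95 to 17.7) against 45.7 CPM (40.5 to 51.3), a log2 ratio of -1.64 (-1.98 to -1.32). The gene lies on chromosome 11 from 52252371 to 52283014 of GRCm38, on the minus strand. The sources used here do not give the deleted part of the gene. A 3′ tag can lie outside a deleted part, so a remaining Tcf7 count does not check the genotype labels. With every cell thinned to 1624 UMIs, a Tcf7 UMI was found in 20.4% of TCRβ Tcf7WT cells, 15.2% of TCRβ Tcf7KO cells, 8.44% of TCRγδ Tcf7WT cells and 2.29% of TCRγδ Tcf7KO cells. Without thinning the shares were 30.03%, 25.8%, 12.8% and 6.02%. Thinning left out 759, 489, 300 and 28 cells. Among epithelial-like cells, which should lack the gene, 0 of 46 thinned cells had a Tcf7 UMI, which allows a share of up to 7.71%, and 3.70% had one without thinning, at a median depth of 9449.5 UMIs. The TCRγδ Tcf7KO share lies under that limit, so it cannot be read as expression. Lef1, the closest relative of Tcf7 in T cells, was 49.5 CPM in TCRβ Tcf7KO and 46.5 CPM in TCRβ Tcf7WT, and under 3 CPM in both TCRγδ libraries.

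**Figure D1:**
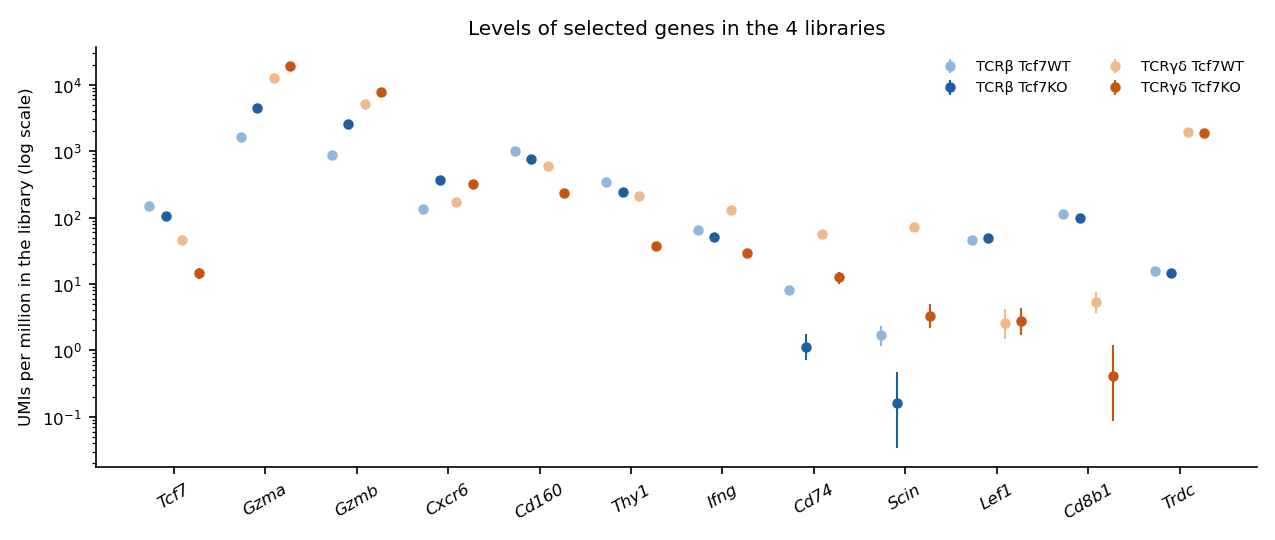
CPM (log scale) of 12 genes in the 4 libraries, each point 1 library and each bar its exact Poisson interval. Gzma and Gzmb sit higher in the Tcf7KO library of each sort, and Tcf7, Cd160, Thy1, Ifng, Cd74 and Scin sit lower.

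Within the TCRβ sort, the comparison addresses which transcripts differ in αβ CD8α+ IELs labelled Tcf7KO. The granzyme genes Gzma, Gzmb and Gzmc were higher in the TCRβ Tcf7KO library, while Gzmk, at 29 against 49 UMIs, had an interval that held 0 (-0.61, -1.33 to 0.078). Gzma, which encodes granzyme A, a protease of cytotoxic granules, was 2.70-fold higher (log2 ratio 1.43, interval 1.42 to 1.45), at 4475 against 1655.5 CPM. Gzmb, which encodes granzyme B, was 2.89-fold higher (1.53, 1.51 to 1.56), at 2541 against 878 CPM. Cxcr6, a chemokine receptor of tissue-resident T cells, was 2.66-fold higher, at 362 against 136 CPM. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was 2.07-fold higher, and Tmem273 was 4.25-fold higher, at 99.2 against 23.4 CPM. Ptpn5, a tyrosine phosphatase, Ier5l, an immediate-early response gene, Errfi1, a feedback inhibitor of EGF receptor signalling, and the noncoding RNA Rn7sk were between 2.07-fold and 2.90-fold higher.

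Among genes with at least 50 CPM in the higher library, those lower in TCRβ Tcf7KO differed by less, epithelial transcripts aside. Sidt1 (-0.77), Acpp (-0.74), Wwp1 (-0.70), Abhd8 (-0.68), Lgals1 (-0.64) and Elk4 (-0.61) were the lowest after epithelial transcripts. Klf2, a transcription factor that keeps T cells in circulation, was 459 against 672 CPM (log2 ratio -0.55, -0.59 to -0.51). Egr1 (-0.55) and Thy1, a surface glycoprotein of T cells, at 239 against 345 CPM (-0.53), were lower by similar amounts. The ends of the ranking also held epithelial transcripts. The mucin Muc2 was 6.94-fold higher in Tcf7KO, Mptx1 was 51.9-fold lower and the keratin Krt8 was 2.42-fold lower. A single cell held 1703 of the 1728 Muc2 UMIs in Tcf7KO, and the 25 UMIs left are fewer than the 275 of Tcf7WT, so the direction rests on that cell. In Tcf7WT 1 cell held 946 of 1549 Mptx1 UMIs. These genes moved with a small cluster of epithelial-like cells, 5 in TCRβ Tcf7KO and 11 in TCRβ Tcf7WT. That cluster held 0.627% and 0.642% of the UMIs.

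The inhibitory and exhaustion, cytotoxic and tissue residency lists were higher in TCRβ Tcf7KO than all or nearly all expression-matched random lists. The inhibitory and exhaustion list had a median log2 ratio of 0.36 (interval 0.27 to 0.45, percentile 100), with 4 of 13 measured members at least 1.5-fold higher. They were Pdcd1, which encodes PD-1 (1.23), Entpd1, which encodes CD39 (0.87), Ctla4 (0.77) and Tigit (0.61). The other members were less than 1.5-fold apart. The cytotoxic list had a median of 0.28 (0.16 to 0.32, percentile 100), with 7 of 20 members at least 1.5-fold higher and 2 lower. Granzyme C (Gzmc, 1.87) was higher and the cytokine gene Tnf (-1.18) was lower. The tissue residency list had a median of 0.20 (0.16 to 0.23, percentile 100), with Bhlhe40 at 0.81 and Prdm1 at 0.53. The cell cycle list had a median of 0.22 (percentile 100), with Mki67 at 0.53, and of -0.061 without cycling cells. The naive and memory list stayed near the other genes, with a median of -0.05 (-0.12 to -0.02, percentile 57.9; 0.02 under TMM scaling and 0.01 under DESeq2 scaling), although its members Igfbp4 (-1.11) and Dapl1 (-1.06), both markers of naive T cells, were lower.

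The other lists lay between -0.14 and 0.18 in the TCRβ sort. Median log2 ratios were 0.10 for type 1 (Th1) genes, 0.09 for cytokine receptors, 0.18 for type 17 genes, 0.16 for regulatory and repair genes, 0.03 for the interferon response and 0.01 for cholesterol and lipid genes. They were -0.02 for NK receptor signalling, -0.03 for T cell receptor signalling, -0.03 for immediate-early and stress genes, -0.03 for Wnt and TCF partners, -0.05 for oxidative phosphorylation and -0.08 for glycolysis. Sex-linked genes had a median of -0.14, with Ddx3y at 0.13. Killer-cell receptor genes moved apart: Klrb1c was 0.69 and Klrk1, which encodes NKG2D, was -0.42. In the coreceptor list, with a median of 0.04, Cd8a was 0.04, Cd8b1 was -0.24 and Cd4, with 88 against 6 UMIs, was 4.02 (2.84 to 5.50). The sign of Cd8b1 was opposite with clusters weighted alike. Without cells with markers of other types, the signs of Cd8a and Cd8b1 were opposite.

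Gzma and Gzmb were also found in a larger share of TCRβ Tcf7KO cells. After thinning, 28.5% of TCRβ Tcf7KO cells (27.3 to 29.7) had a Gzma UMI against 9.15% of TCRβ Tcf7WT cells (8.47 to 9.85), and 46.6% against 21.5% had a Gzmb UMI. Without thinning, the Gzma shares were 32.5% and 9.94% and the Gzmb shares 50.8% and 24.1%. In epithelial-like cells the thinned shares were 8.70% (2.42 to 20.8) for Gzma and 10.9% (3.62 to 23.6) for Gzmb. Those cells are pooled over all libraries, and 38 of the 54 before thinning came from the TCRγδ libraries, where both genes are higher, so they do not give the background of the TCRβ libraries. Naive or central memory-like cells of the same library, found by the clustering described next and used here after the values were seen, gave thinned shares of 8.99% (6.31 to 12.3) in Tcf7KO and 2.53% (1.42 to 4.14) in Tcf7WT for Gzma. For Gzmb they gave 25.7% (21.3 to 30.4) and 8.43% (6.32 to 10.97). The shares over all cells lay above these limits in both libraries. The share in naive or central memory-like cells was itself higher in Tcf7KO, so background is not excluded as part of the difference in shares. Cells were then clustered without the genes that stood at least 1.5-fold apart between genotypes. A cytotoxic resident IEL-like cluster held 21.4% of TCRβ Tcf7KO cells (20.3 to 22.5) and 11.8% of TCRβ Tcf7WT cells (11.1 to 12.5). Its name still rests on Gzma and Gzmb, so these shares are not independent of the difference in those genes. A naive or central memory-like cluster held 7.14% (6.49 to 7.83) and 8.38% (7.77 to 9.02), and 7.88% and 7.91% when clustered on all variable genes. Gzma was higher in Tcf7KO within the cytotoxic-like cluster, at 13931 against 10621 CPM. In the largest cluster, which has no cell type name, it stood at 901 against 51.5 CPM. Clusters were made from unthinned cells. The cytotoxic-like cluster had a median of 3748.5 UMIs per cell, against 2341 in the largest cluster. Median UMIs per cell were also higher in TCRβ Tcf7KO than in TCRβ Tcf7WT, at 2860 against 2431. The part of depth in the cluster shares was not tested.

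**Figure D2:**
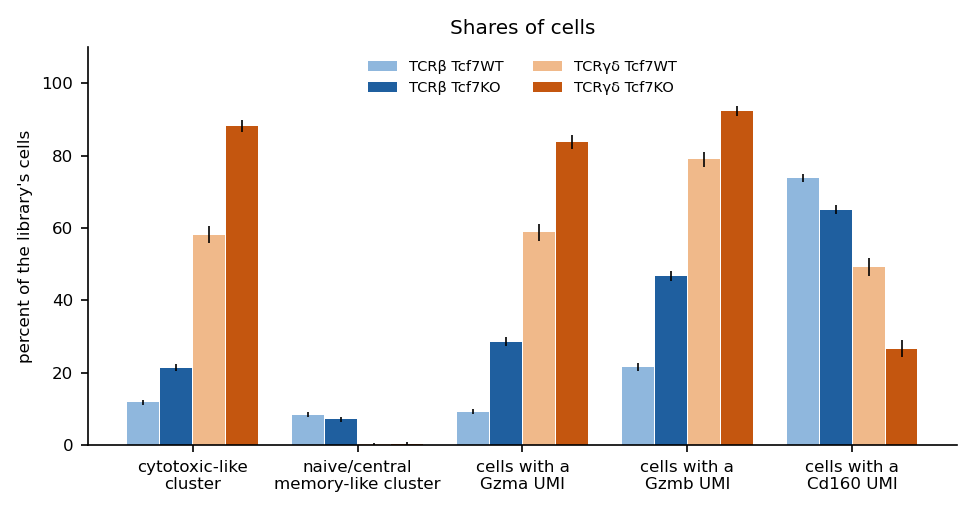
Percent of each library's cells in the cytotoxic-like and the naive or central memory-like cluster, and percent with a Gzma, Gzmb or Cd160 UMI after thinning to 1624 UMIs. Cells were not thinned for the cluster shares. Bars are single libraries with exact Clopper-Pearson intervals; the cytotoxic-like share is 21.4% and 88.3% in the Tcf7KO libraries against 11.8% and 58.2% in the Tcf7WT libraries.

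Within the TCRγδ sort, the comparison addresses the same question for γδ CD8α+ IELs. Several transcripts that were abundant in the TCRγδ Tcf7WT library were scarce in the TCRγδ Tcf7KO library. Scin, which encodes an actin-severing protein, was 21.3-fold lower (log2 ratio -4.41, -5.07 to -3.82), at 3.34 against 71.2 CPM. The MHC class II genes H2-Eb1 (-3.86) and Cd74, the invariant chain (-2.19), were lower, as was H2-Eb2 (-1.68). A single cell held 80 of the 90 Cd74 UMIs in Tcf7KO, and 10 remain without it, against 354 in Tcf7WT. Thy1 was 5.74-fold lower, at 36.9 against 212 CPM, and Ifng, which encodes interferon-γ, was 4.51-fold lower, at 29.0 against 131 CPM. Lgals1, which encodes galectin-1, was 11.9-fold lower. Ms4a4b (-2.30), Sh3kbp1 (-2.07) and Fam241a (-1.63) completed the 10 lowest.

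Gzma and Gzmb, which lie outside the 10 highest here and were chosen after their values were seen, were higher in the TCRγδ Tcf7KO library too. Gzma stood at 18928 against 12475 CPM (log2 ratio 0.60, 0.59 to 0.61) and Gzmb at 7810 against 5159 CPM (0.60, 0.58 to 0.62). The 10 highest genes were led by epithelial transcripts, among them Reg4 (3.36), Cyp2c55 (3.05), Car1 (3.004), Retnlb (2.90), Muc2 (2.49), Muc3 (2.37) and Gpx2 (2.26). In this library 20 epithelial-like cells held 6.19% of all UMIs, against 1.65% in 18 cells of TCRγδ Tcf7WT. Without those cells, the highest gene was Tmprss6, which encodes a membrane serine protease, at 2.13. It was followed by Fcgr3, an Fc receptor (1.63), Cnih2 (1.55), Errfi1 (1.43), Ptpn5 (1.42), C1qtnf6 (1.37), Ccrl2 (1.35), Ier5l (1.31), Tnfrsf9 (1.30) and the killer-cell receptor gene Klrb1c (1.17).

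By gene list, immediate-early and stress genes had a median log2 ratio of -0.25 in the TCRγδ sort (-0.32 to -0.20, percentile 0), with Fos at -0.67, Fosb at -0.68 and Jun at -0.61. Without cells with markers of other types, a choice that leaves 314 cells in TCRγδ Tcf7KO, that median was 0.021. The interferon response list had a median of -0.31 (-0.33 to -0.09, percentile 0), with Irf1 at -0.49. The T cell receptor signalling list had a median of -0.17 (-0.20 to -0.11, percentile 0.23), with 4 of 17 members at least 1.5-fold lower. Those members included Cd6 (-2.68), Themis (-1.66) and Lat, an adaptor downstream of the receptor (-1.38). The cytotoxic list had a median of -0.01 (-0.05 to 0.13, percentile 52.3) over members that went both ways. Gzmk (-5.27) and Tnf (-1.72) were lower and Gzmc (0.94) was higher. The naive and memory list also had a median near 0, at -0.04 (-0.24 to 0.23, percentile 40.9), with Il7r, the interleukin-7 receptor, at -2.56 and Satb1 at 1.01. With clusters weighted alike, the signs of Cd6 (1.09), Themis (0.27), Il7r (0.36) and Ms4a4b (0.53) were opposite. That choice used 3 clusters here, and Cd6 and Il7r had only 24 and 23 UMIs in TCRγδ Tcf7KO.

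The NK receptor signalling list had a median of -0.035 in the TCRγδ sort (-0.18 to 0.23, percentile 38.1) over members that went both ways. Cd160 stood at 236 against 595 CPM (-1.33), Klrk1 at -2.41 and Klrg1 at -1.83, while Klra9 was 1.37. The tissue residency list had a median of -0.019 (-0.084 to 0.049, percentile 44.6), with the gut-homing receptor Ccr9 at -1.14 and Cxcr6 at 0.87. The inhibitory and exhaustion list had a median of 0.16 (-0.13 to 0.22, percentile 98.6) over members that went both ways. Its member Havcr2 had 87 UMIs in TCRγδ Tcf7WT but is not listed for TCRγδ Tcf7KO, so it has no ratio and is left out. Counted as lower in Tcf7KO, it would bring the median and the percentile down, so they depend on the listing. Pdcd1 (3.08, from 49 against 5 UMIs) and Entpd1 (0.54) were higher, and Cish (-0.45) and Ctla4 (-0.32) were lower, but with clusters weighted alike Cish was 0.083 and Ctla4 was 1.14. The cell cycle list had a median of 0.48 (percentile 100), with Birc5 at 1.67. It moved with the epithelial-like cells and had a median of 0.21 without them, and of -0.17 without cycling cells. The regulatory and repair list, led by Vegfa (2.75) and the growth factor gene Areg (2.53), moved with them in the same way, with a median of 0.75 and of 0.33 without them. The type 17 list had 5 measured members and a median of 1.197, with Tmem176a at 1.79 and Rora at -1.59.

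After thinning, a Gzma UMI was found in 83.8% of TCRγδ Tcf7KO cells (81.8 to 85.7) and in 58.8% of TCRγδ Tcf7WT cells (56.3 to 61.2). A Cd160 UMI was found in 26.6% and 49.2%, and an Ifng UMI in 3.64% and 9.89%. Without thinning these shares were 87.8% and 61.4% for Gzma, 46.9% and 60.0% for Cd160, and 6.22% and 15.04% for Ifng. Epithelial-like cells had a thinned share of 4.35% for Cd160 and of 0 of 46 cells for Ifng, which allows up to 7.71%. The Tcf7KO share of Ifng is under that limit. Clustered without the genes that stood apart between genotypes, 88.3% of TCRγδ Tcf7KO cells (86.6 to 89.9) fell in the cytotoxic resident IEL-like cluster, against 58.2% of TCRγδ Tcf7WT cells (55.9 to 60.4). As in the TCRβ sort, that cluster is named by Gzma and Gzmb, so its share is not independent of them. The naive or central memory-like cluster held 5 and 3 cells. Here too the cells were not thinned for clustering. Median UMIs per cell were 4366 in TCRγδ Tcf7KO and 3188 in TCRγδ Tcf7WT, and the part of depth in the cluster shares was not tested.

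**Figure D3:**
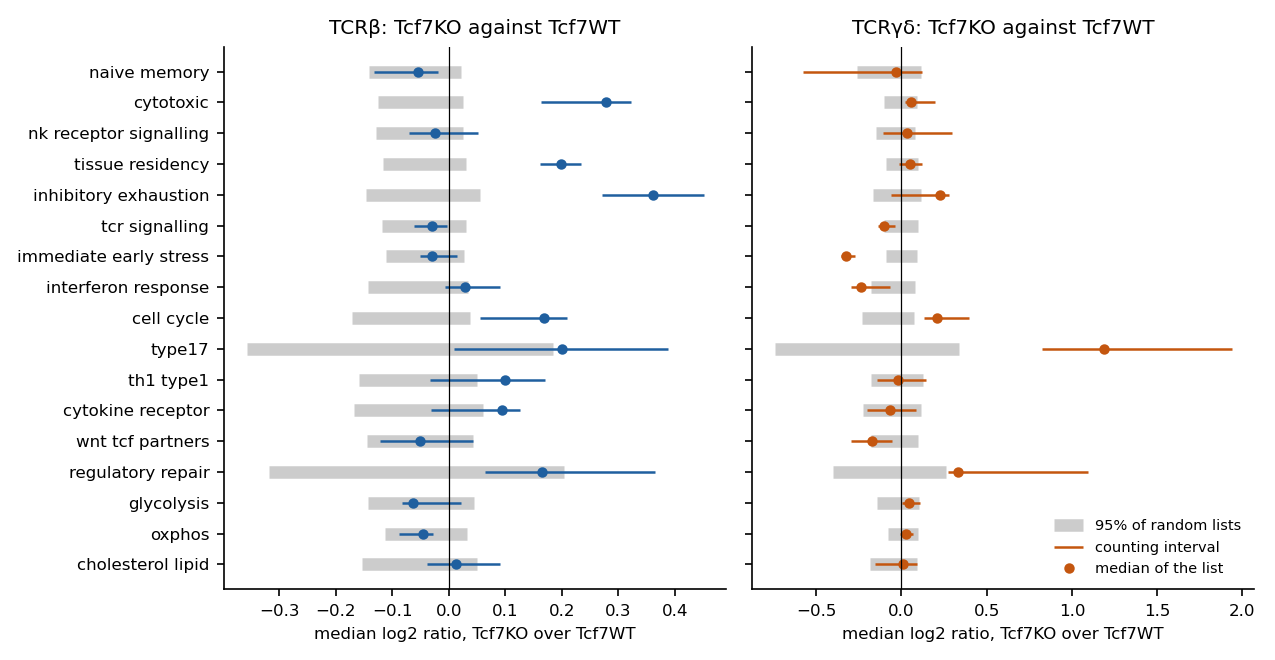
Median log2 ratio, Tcf7KO over Tcf7WT, of 17 gene lists in each sort without the epithelial-like cluster. Points are medians, lines their counting intervals and grey bars the range of 95% of random lists; the inhibitory, cytotoxic and tissue residency medians lie to the right of the grey bars in the TCRβ sort, and the immediate-early and stress median lies to the left in the TCRγδ sort.

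Setting the genotype ratios of the sorts side by side addresses whether αβ and γδ cells differed in the same genes. Across 9108 genes with at least 100 UMIs in each comparison, the log2 ratios had a Pearson r of 0.322 and a Spearman rho of 0.335, and 62.8% had the same sign. Genes are not independent replicates, so the counts expected under independence below are a yardstick and no test. The labels pair no libraries, so shared mice or a shared preparation of the sorts cannot be told apart from genotype. One sort is therefore not a replicate of the other. The epithelial-like cells weighed on r. Without them r was 0.447 and 63 genes were at least 1.5-fold higher in both Tcf7KO libraries, where 2.84 would be if the sorts were independent. Likewise, 51 were at least 1.5-fold lower in both, where 3.94 would be, and these still held transcripts of gut epithelium such as Fabp2, Tff3 and Zg16. In opposite directions, 12 were higher in the TCRβ sort and lower in the TCRγδ sort, and 2 were the other way round. In this set Gzma, Gzmb, Gzmc, Cxcr6, Tnfrsf9, Tmprss6, Ptpn5, Errfi1, Entpd1 and Bhlhe40 were among those higher in both, and Lgals1, Cd74, H2-Eb1, H2-Ab1 and Tnf among those lower, all picked after the values were seen. With the epithelial-like cells kept, 70 genes were higher and 34 lower in both, where 4.93 and 3.11 would be, and the opposite directions turned to 2 and 24. With cycling cells left out and epithelial-like cells kept, r was -0.0419, and with both left out it was 0.440.

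**Figure D4:**
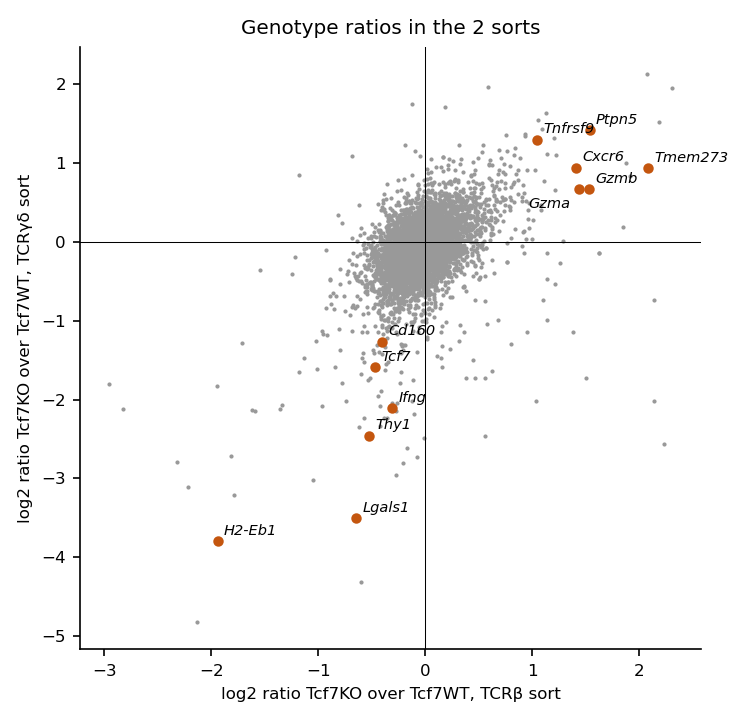
Log2 ratio, Tcf7KO over Tcf7WT, of 9108 genes in the TCRβ sort (horizontal axis) and in the TCRγδ sort (vertical axis), without the epithelial-like cluster. Each point is a gene; Gzma, Gzmb, Cxcr6, Tnfrsf9, Ptpn5 and Tmem273 lie to the upper right, and Lgals1 and H2-Eb1 to the lower left.

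Between the Tcf7WT libraries, the sorts were compared to set γδ against αβ CD8α+ IELs. Cytotoxic and MHC class II transcripts were higher in the TCRγδ Tcf7WT library and naive T cell transcripts were lower. Gzma was 7.54-fold higher than in TCRβ Tcf7WT (log2 ratio 2.91, 2.90 to 2.93), Scin was 42.5-fold higher, Cd74 was 7.07-fold higher and H2-Eb1 was 6.58-fold higher. Prdm1, which encodes the transcription factor Blimp-1, was 5.97-fold higher. Sprr2a3 was 16.2-fold higher (log2 ratio 4.02) and was 1.16 without the epithelial-like cells, which held 1.65% of the UMIs in TCRγδ Tcf7WT and 0.642% in TCRβ Tcf7WT. The costimulatory receptor gene Cd28 was 0.646 against 92.4 CPM (-7.16, -9.04 to -5.80), Cd8b1, which encodes the CD8β chain, was 5.33 against 114 CPM (-4.42), and Cd2 was 16.1 against 201 CPM (-3.64). S100a4 (-6.20), Cldn10 (-4.37) and Klra6, an inhibitory Ly49 receptor gene (-3.31), were also lower. The γδ receptor constant genes had a median of 2.19, with Trdc at 1946 against 15.4 CPM, and the αβ constant genes had a median of -0.77. Trbc2 remained at -0.77. The naive and memory list had a median of -1.92 (-2.03 to -1.79, percentile 0), with S1pr1 at -5.33 and Lef1 at -4.17. The cytotoxic list had a median of 0.64 (0.55 to 0.73, percentile 100), with 10 of 20 members at least 1.5-fold higher. With clusters weighted alike these medians were -0.91 and 0.11.

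Between the Tcf7KO libraries, the sorts stood apart along the same lists. The naive and memory list had a median of -2.24 in TCRγδ Tcf7KO over TCRβ Tcf7KO (-2.44 to -1.95, percentile 0), and the cytotoxic list had a median of 0.27 (0.19 to 0.33, percentile 100). With clusters weighted alike these medians were -0.83 and -0.013. Gzma was higher at 2.08 and Gzmb at 1.62. Cd8b1 had 3 UMIs in TCRγδ Tcf7KO and stood at 96.8 CPM in TCRβ Tcf7KO (-7.86, -10.14 to -6.31). Cd28 (-5.67), Cldn10 (-4.67), Ms4a4b (-4.30), Klra6 (-3.25) and Cd2 (-3.10) were the other lowest genes. Among the 6 highest genes were Mptx1, Car1, Cyp2c55, Sprr2a3 and Guca2a, between 51.8-fold and 278-fold higher. They moved with the epithelial-like cells, which held 6.19% of the UMIs in TCRγδ Tcf7KO and 0.627% in TCRβ Tcf7KO. Without those cells the highest genes were Tmprss6 (3.03), Cnih2 (2.79), Plek (2.72), the actin-capping gene Capg (2.56), Stk32c (2.49) and Tnfrsf9 (2.27). The immediate-early and stress list had a median of -0.34 (percentile 0).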

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

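All of the tests here were chosen after the results were seen. Some named genes stood at least 1.5-fold apart between genotypes in opposite directions in the sorts, lower in the TCRβ Tcf7KO library and higher in the TCRγδ Tcf7KO library. The TCRγδ log2 ratio minus the TCRβ log2 ratio was 7.26 for Mptx1, 6.71 for Car1, 5.73 for Areg, 5.32 for Cyp2c55, 2.81 for Krt8 and 2.65 for Fabp2. This difference between the sorts was not tested, since each group is 1 library. Apart from Areg these are transcripts of gut epithelium. Without the epithelial-like cluster, the TCRγδ ratios were -0.19 for Mptx1, -0.11 for Car1, 1.22 for Areg, -0.15 for Cyp2c55, -1.02 for Krt8 and -1.47 for Fabp2, and Areg alone of these was still at least 1.5-fold lower in TCRβ (-1.73) and at least 1.5-fold higher in TCRγδ. With cycling cells left out as well, its TCRγδ ratio was -0.79. With all cells kept, Areg rested on few cells. It had 7 UMIs in TCRβ Tcf7KO and 71 in TCRβ Tcf7WT, where 1 cell held 29. In TCRγδ Tcf7WT 1 cell held 17 of 32 UMIs, and in TCRγδ Tcf7KO 1 cell held 66 of 214. No biological explanation was tested.

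Gzma and Gzmb were higher in both Tcf7KO libraries. Free RNA from lysed cells could raise a transcript in every droplet of a library. In the TCRβ sort, the upper limit of Gzma per naive or central memory-like cell was subtracted from the Tcf7KO library alone, and the Gzma log2 ratio went from 1.43 to 1.38 and that of Gzmb from 1.53 to 1.28. In the TCRγδ sort, with epithelial-like cells in that role, they went from 0.60 to 0.58 and from 0.60 to 0.57. All 4 stayed above 0.5 of the ratio before, a bound set after the values were seen, which argues against free RNA as the whole source. A difference between single libraries or mice stays open, since there is 1 library per group and genotype cannot be told apart from it.

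MHC class II genes and Scin were lower in the TCRγδ Tcf7KO library. The sort on CD3, CD8α and the γδ receptor would remove antigen-presenting cells and B cells, and such cells could give this pattern only if they passed it. In TCRγδ Tcf7WT 97.4% (96.4 to 98.2) of 1315 UMIs of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 lay in cells with a Trdc UMI, against 96.3% of all UMIs. Of the library's 1888 cells, 1795 had a Trdc UMI, so this share alone says little. For Scin the share was 90.5% (87.3 to 93.0), below that of all UMIs. The 142 cells with at least 3 UMIs of the MHC class II genes held 59.8% of those UMIs. Their Trdc level was 1.04 times (0.98 to 1.11) that of the other cells. Their median depth was 1.203 times that of the others (1.14 to 1.26, from 1000 redraws of the cells), under the 1.5 set for doublets. The Trdc level argues against antigen-presenting cells or B cells on their own as the source of the UMIs in these 142 cells. The depth does not exclude doublets with a cell of few UMIs, since its interval lies above 1. Free RNA was not tested for these genes. The minimum of 3 UMIs was chosen, and a first, weaker form of both tests was replaced, after the values were seen. In TCRγδ Tcf7KO a single cell held 63.2% of the 174 MHC class II UMIs, and a difference between single libraries or mice stays open with 1 library per group.

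Cd4 UMIs were found in both Tcf7KO libraries, 88 in TCRβ and 70 in TCRγδ, against 6 in TCRβ Tcf7WT, while TCRγδ Tcf7WT does not list the gene. The sort on CD8α would remove CD4 T cells without CD8α, which could give this pattern if they passed it and would carry little Cd8a. Cells with a Cd4 UMI had a Cd8a level 1.32 times (1.21 to 1.44) that of the other cells in TCRβ Tcf7KO and 1.33 times in TCRγδ Tcf7KO, which argues against CD4 T cells without CD8α. T cells with both CD4 and CD8α would pass the sort and carry Cd8a, so the Cd8a level cannot speak for or against them. No cell had more than 2 Cd4 UMIs. A difference between single libraries or mice stays open with 1 library per group.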

How the results depend on the processing

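The direction of most values held under the alternatives. The 150 log2 ratios of genes named in the text had 1949 alternative values, of which 1445 lay within the counting interval, 440 lay past it with the same sign or from a ratio whose interval held 0, and 64 had the opposite sign. Over all 396 gene ratios that the naming rule takes, the counts were 4077, 917 and 152 of 5146. The opposite signs were set out gene by gene for the genes of the text alone, a limit chosen after those counts were seen. The counts differed by alternative. Without Scrublet doublets, and with a total without receptor and immunoglobulin genes, all 150 ratios of the text lay within the interval. Those choices hardly change the data, so their share of the counts above says little. With clusters weighted alike, 22 lay within the interval, 111 lay past it and 17 had the opposite sign. Without cells with markers of other types these counts were 51, 88 and 10 of 149. The 82 list medians had 1230 alternative values, with 926 within the interval, 284 past it and 20 of opposite sign. Leaving out the epithelial-like cluster, alone or with cycling cells, and leaving out the highest doublet scores were chosen after seeing the data. In what follows, the value under the alternative stands after each name, as a log2 ratio unless it is a correlation or a share. With TMM scaling, values lay past their counting interval for naive and memory list 0.017, cytotoxic list 0.35 within the TCRβ sort. With DESeq2 scaling, values lay past their counting interval for naive and memory list 0.011, cytotoxic list 0.34 within the TCRβ sort. With each cell weighing the same, the sign was opposite for Fabp2 -0.54, Krt8 -0.43 within the TCRγδ sort. Larger than counting error was the shift for naive and memory list -2.05, cytotoxic list 0.73 within Tcf7WT, between the sorts, and across genes for Pearson r 0.403. With cells of 500 to 3500 genes alone, the sign was opposite for Muc2 -2.38, cell cycle list -0.019 within the TCRβ sort, and for Birc5 -0.52, Car1 -0.081, Cyp2c55 -0.16, Fabp2 -2.31, Gpx2 -0.56, Krt8 -1.42, cell cycle list -0.36 within the TCRγδ sort, and for cell cycle list -0.65 within Tcf7KO, between the sorts. Values then lay past their interval for naive and memory list -2.48, cytotoxic list 0.36 within Tcf7KO, between the sorts, and across genes for Pearson r 0.46. Without cells with markers of other types, the sign was opposite for Cd8a -0.043, Cd8b1 0.0096, Cyp2c55 0.56, Fabp2 0.56, Mki67 -0.42, Muc2 -0.44 within the TCRβ sort, and for Car1 -0.35, Krt8 -1.93, Muc2 -0.35, Reg4 -0.086, immediate-early list 0.021, cholesterol list -0.13 within the TCRγδ sort, and for cell cycle list -0.061, type 1 list -0.036, glycolysis list -0.0071 within Tcf7KO, between the sorts. Larger than counting error was the shift for naive and memory list 0.039 within the TCRβ sort, and for cytotoxic list 0.21 within the TCRγδ sort, and for naive and memory list -2.09 within Tcf7WT, between the sorts, and for naive and memory list -1.82, cytotoxic list 0.43 within Tcf7KO, between the sorts, and across genes for Pearson r 0.274. Without cycling cells, the sign was opposite for Mki67 -0.82, Muc2 -3.34, cell cycle list -0.061 within the TCRβ sort, and for Birc5 -0.17, Tff3 0.43, cell cycle list -0.17 within the TCRγδ sort, and for cell cycle list -0.18 within Tcf7KO, between the sorts, and across genes for Pearson r -0.0419. With clusters weighted alike, the sign was opposite for Cd8b1 0.34, Krt8 0.33, Mki67 -0.26 within the TCRβ sort, and for Car1 -0.17, Cd6 1.09, Cish 0.083, Ctla4 1.14, Cyp2c55 -0.039, Fabp2 -0.39, Il7r 0.36, Krt8 -1.05, Mptx1 -0.33, Ms4a4b 0.53, Muc2 -0.91, Muc3 -0.49, Retnlb -0.43, Themis 0.27, cholesterol list -0.014 within the TCRγδ sort, and for cytotoxic list -0.013, cell cycle list -0.12, type 1 list -0.17 within Tcf7KO, between the sorts. The counting interval was passed for Tcf7 -0.35, naive and memory list 0.0092 within the TCRβ sort, and for cytotoxic list 0.24 within the TCRγδ sort, and for naive and memory list -0.91, cytotoxic list 0.11 within Tcf7WT, between the sorts, and for naive and memory list -0.83 within Tcf7KO, between the sorts, and across genes for Pearson r 0.339. With thinned cells, the sign was opposite for Fabp2 -0.24, cholesterol list -0.0053 within the TCRγδ sort. The interval did not hold the value for naive and memory list -0.17 within the TCRβ sort, and for naive and memory list 0.30, cytotoxic list 0.16 within the TCRγδ sort, and for naive and memory list -1.90, cytotoxic list 0.39 within Tcf7KO, between the sorts. Without the epithelial-like cluster, the sign was opposite for Cyp2c55 0.26, Krt8 0.20 within the TCRβ sort, and for Car1 -0.11, Cyp2c55 -0.15, Fabp2 -1.47, Krt8 -1.02, Mptx1 -0.19, Muc2 -1.05, Muc3 -0.26, Reg4 -2.73 within the TCRγδ sort, and for cell cycle list -0.029 within Tcf7KO, between the sorts. The counting interval was passed for naive and memory list -2.55, cytotoxic list 0.35 within Tcf7KO, between the sorts, and across genes for Pearson r 0.447. Without the epithelial-like cluster and cycling cells, the sign was opposite for Cyp2c55 0.29, Krt8 0.14, Mki67 -0.81, cell cycle list -0.066 within the TCRβ sort, and for Areg -0.79, Birc5 -0.14, Car1 -0.082, Cyp2c55 -0.14, Fabp2 -1.40, Krt8 -1.07, Mptx1 -0.22, Muc2 -0.95, Muc3 -0.14, Reg4 -2.72, cell cycle list -0.14 within the TCRγδ sort, and for cell cycle list -0.18 within Tcf7KO, between the sorts. The interval did not hold the value for naive and memory list -2.28 within Tcf7WT, between the sorts, and for cytotoxic list 0.37 within Tcf7KO, between the sorts, and across genes for Pearson r 0.44. With at least 100 UMIs, values lay past their counting interval for cytotoxic list 0.75 within Tcf7WT, between the sorts. With at least 20 UMIs, values lay past their counting interval across genes for Pearson r 0.216. With at least 1000 UMIs, values lay past their counting interval across genes for Pearson r 0.408. Clustering settings moved the shares of cells. With the genes that stood apart left out and 1000 variable genes, the naive or central memory-like share was 9.67% in TCRβ Tcf7WT, 8.76% in TCRβ Tcf7KO and 0.530% in TCRγδ Tcf7WT, and the cytotoxic-like share was 19.7% in TCRβ Tcf7KO and 55.3% in TCRγδ Tcf7WT. At a Leiden resolution of 1 the cytotoxic-like share was 9.52%, 19.6%, 45.2% and 76.5% in TCRβ Tcf7WT, TCRβ Tcf7KO, TCRγδ Tcf7WT and TCRγδ Tcf7KO, and at 0.3 it was 11.04% in TCRβ Tcf7WT. Without Scrublet doublets it was 54.6% in TCRγδ Tcf7WT. Clustering on all variable genes, as planned, gave naive or central memory-like shares of 7.88% in TCRβ Tcf7KO and 7.91% in TCRβ Tcf7WT, with overlapping intervals. Its variants gave 7.99% and 8.06% at resolution 1 and 7.71% and 7.76% at resolution 0.3. The order turned to 8.47% and 8.18% with 1000 variable genes and to 7.93% and 7.74% without doublets, so the planned clustering does not settle the order of the TCRβ libraries. The opposite sign of the correlation without cycling cells goes with the epithelial-like cells left in, since leaving out both gave 0.440. The signs of Car1, Cyp2c55, Fabp2, Krt8, Mptx1, Muc2, Muc3 and Reg4 in the TCRγδ sort depend on the 38 epithelial-like cells there, since leaving those out reversed them. For every other value that moved or reversed, the cause was not tested. Leaving out cells with markers of other types kept 3741, 2294, 733 and 314 cells, fewer than were left out in each library. Scrublet called 1, 0, 0 and 29 cells doublets at its automatic threshold, so few that this threshold is in doubt. The shares without these cells, given above, moved all the same, and the cause was not tested. The files hold no mitochondrial genes, so no mitochondrial filter was run. No paired analysis was possible because each group is 1 library and the labels pair none. Leaving out a replicate was not possible for the same reason. Depth limits genes with few UMIs: Cd8b1 had 3 UMIs in TCRγδ Tcf7KO and Gzmk had 6.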

Other observations

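The variable segments of the γ and δ receptor chains given here are named as in the files and were chosen after their values were seen. Some stood level between the TCRγδ libraries and others did not. Tcrg-V7 stood at 20.02 CPM (16.6 to 23.9) in TCRγδ Tcf7WT and 22.8 CPM (19.5 to 26.6) in TCRγδ Tcf7KO. Trdv5 stood at 32.3 CPM (27.96 to 37.1) and 33.7 CPM (29.6 to 38.2). Tcrg-V1 stood at 94.3 CPM (86.8 to 102) and 41.2 CPM (36.6 to 46.2). Tcrg-V1 was also found in the TCRβ libraries, at 89.8 CPM in Tcf7WT and 69.9 CPM in Tcf7KO, so its count is not limited to γδ cells. Trdv2-2 stood at 24.4 CPM (20.6 to 28.6) in TCRγδ Tcf7WT and 14.2 CPM (11.6 to 17.2) in TCRγδ Tcf7KO. In TCRβ Tcf7WT and Tcf7KO it was scarcer, at 3.55 and 3.32 CPM. Tcrg-V4 was also lower in TCRγδ Tcf7KO, at 7.52 against 14.7 CPM, and stood at 10.3 CPM in both TCRβ libraries. No explanation was tested.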
